A study of Homo sapiens with 9 samples.

How the data were processed

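Total RNA from untreated cultures of 8 human neuroblastoma lines and 1 non-malignant sample of bone marrow mesenchymal stem cells was hybridised to 1-colour Affymetrix whole-transcript arrays, with 1 array per sample. Per the labels, BE(2)c, SK-N-DZ, IMR-32, SK-N-BE(2)c and CHP-212 are MYCN-amplified, SK-N-AS, SH-SY5Y and SK-N-SH are not, and the mesenchymal stem cells are a control. The mesenchymal stem cells are called stromal cells below. A further non-malignant line that the series' design mentions was not analysed here.

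The values are log2 expression levels per probeset that the authors made with RMA (background correction, quantile normalization and probeset summary), and RMA and Partek are the tools named in the submitters' processing notes. Versions and a genome build are not given in the sources used here. The array medians lay between 7.30 and 7.41 log2 units, so the values were not centred per gene. The log base, which the sources used here do not state, was taken as 2 because every array spanned values from about 2 to 15, the usual range of log2 RMA output. Because quantile normalization gives all arrays nearly the same distribution, a change in total RNA per cell would not be visible. Array values carry no read depth, and the precision of each comparison is limited by the number of arrays. Levels of different probesets were not set against each other, because probesets differ in brightness.

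Of 33297 probesets, 19460 had exactly 1 gene symbol in the platform annotation, 1754 had several and 12083 had none. Only those with 1 symbol were used, and 99.8% of them matched a current symbol by NCBI gene number in a RefSeq gene table of assembly GRCh38. That table was used for names and for the order of neighbouring genes only. For each gene the probeset with the highest mean over the 9 arrays was taken, which gave 18391 genes. The 26 sex-specific genes found were left out of every step. A gene was tested if it lay above its array's 40th percentile of all probesets on at least 3 of the 8 neuroblastoma arrays, or, for the stromal comparison, on at least 3 of the 9 arrays or on the stromal array.

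MYCN-amplified and non-amplified lines were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The stromal array was left out of that fit. Gene lists, 24 in number and holding 503 members of which 449 had a usable probeset, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 23 lists. Camera with the correlation estimated per list, and fry, were run as alternatives. An exact permutation test of each list's mean over the 56 splits of the lines into 5 and 3 was added after the data were seen. MYCN itself was tested with an exact two-sided permutation test over the same splits, whose smallest possible p is 0.0179.

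The stromal comparison has 1 stromal array and no test. A gene was called where the mean of the 8 lines differed from the stromal value by at least 4-fold and the stromal value lay outside the range of the lines. A list was called apart where its median difference fell below the 2.5th or above the 97.5th percentile of 10000 random lists of the same size matched on mean expression. These calls describe the arrays and say nothing of other stromal donors.

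Named genes are the 10 largest rises, MYCN among them, and the 10 largest falls among genes past the threshold. In the stromal comparison they are the 10 largest differences each way among called genes. In each list they are members past the threshold or, failing that, up to 4 with the smallest p (in the stromal comparison, the largest differences). Among the largest differences, unnamed loci, non-coding RNAs (MYCNOS among them, which is annotated as one), pseudogenes and antisense or open-reading-frame symbols were skipped. Members of the lists were named without this rule. The array platform is a single type, the labels give no batch or date, and no pair of arrays held the same values (at most 12 identical probeset values per pair).

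The fits were tested on simulated tables of the same size as the 5 against 3 comparison, with 13661 genes and the measured means and spreads. The gene test recovered 35 of 68 genes changed by 1 log2 unit, 53 of 66 changed by 2 units and 62 of 66 changed by 4 units, with 11 false calls among 161. The list test recovered a list raised by 1 log2 unit in 50 of 50 simulated tables and made a false call in 3 of them. The simulated genes were independent, so that test does not cover lists whose members vary together between lines. The simulated lines were independent too, so neither test covers the related lines among the real arrays.

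Alternatives covered the brightness filter, renormalization, the choice of probeset, eBayes options, array weights, averaging or blocking of related lines, a block on the replicate number, leaving out each line in turn, other thresholds and, added after the data were seen, leaving out SH-SY5Y together with CHP-212. BE(2)c and SK-N-BE(2)c are by their names 1 parental line, and SH-SY5Y is a known subline of SK-N-SH, so 6 parental lines stand behind the 8 arrays. Each line is 1 culture, and the limma p-values of single genes rest on the spread between lines. Camera at its preset correlation compares the members of a list or window with other genes. Its p-values therefore do not measure how far the mean of a list or window varies between lines. Windows of 50 neighbouring genes were tested with camera after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.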

Results

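The series measured the expression of protein-coding and other genes in 8 untreated neuroblastoma cell lines and in bone marrow mesenchymal stem cells. Neuroblastoma is a childhood tumour of the sympathetic nervous system, and amplification of MYCN, a transcription factor gene of the MYC family, marks an aggressive form of it. There were 5 MYCN-amplified lines (BE(2)c, SK-N-DZ, IMR-32, SK-N-BE(2)c and CHP-212), 3 lines without the amplification (SK-N-AS, SH-SY5Y and SK-N-SH) and 1 stromal sample, each measured on 1 array as log2 RMA values. The design implies a comparison of amplified with non-amplified lines and a comparison of the neuroblastoma lines with the non-malignant cells.

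MYCN itself separated the groups. Its level was 13.90 ± 0.15 log2 units in the amplified lines (SD, n = 5) and 8.28 ± 1.15 in the non-amplified lines (SD, n = 3), a difference of 5.62 log2 units or 49.1-fold (exact two-sided permutation p = 0.0179, the smallest that 56 splits allow). The 5 amplified lines lay between 13.68 and 14.05. Among the others, MYCN stood at 7.08 in SK-N-AS, 8.40 in SK-N-SH and 9.37 in SH-SY5Y, and the stromal sample read 7.21. No label was contradicted by these levels. With related lines averaged, which leaves 4 against 2, the difference was 5.89 and the exact permutation p was 0.0667, the smallest that 15 splits allow.

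MYC, the family member best known outside neuroblastoma, ran the opposite way and fell by 3.37 log2 units in the amplified lines (6.85 ± 0.25 against 10.22 ± 0.21, SD, n = 5 and n = 3; limma adjusted p = 0.0005). The stromal cells had 9.81. NRIP1, a corepressor of nuclear receptors, was 5.53 log2 units higher in the amplified lines (10.59 ± 0.43 against 5.06 ± 0.44; limma adjusted p = 0.0005), and its stromal level was 9.87. The lower group mean lay under the 40th percentile of every array (6.70 to 6.81) in NRIP1 and 5 more of 20 named genes. The 5 were RNF217, FOXR2, TNFAIP6, CCDC146 and SLC44A3, and background limits the size of a difference there. The MYC mean in the amplified lines, 6.85, lay only just above that range, so background may limit the size of its fall too. In total 82 of 13661 genes passed the threshold, 44 higher and 38 lower in the amplified lines, and 2426 genes (17.8%) had an unadjusted p under 0.05. The groups did not overlap in 1809 genes (13.2%), where chance gives 3.57% if all lines are independent. The real split keeps both pairs of related lines together, and related lines that behave alike would raise the share expected by chance. The excess over 3.57% therefore cannot be put down to MYCN status.

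**Figure D1:**
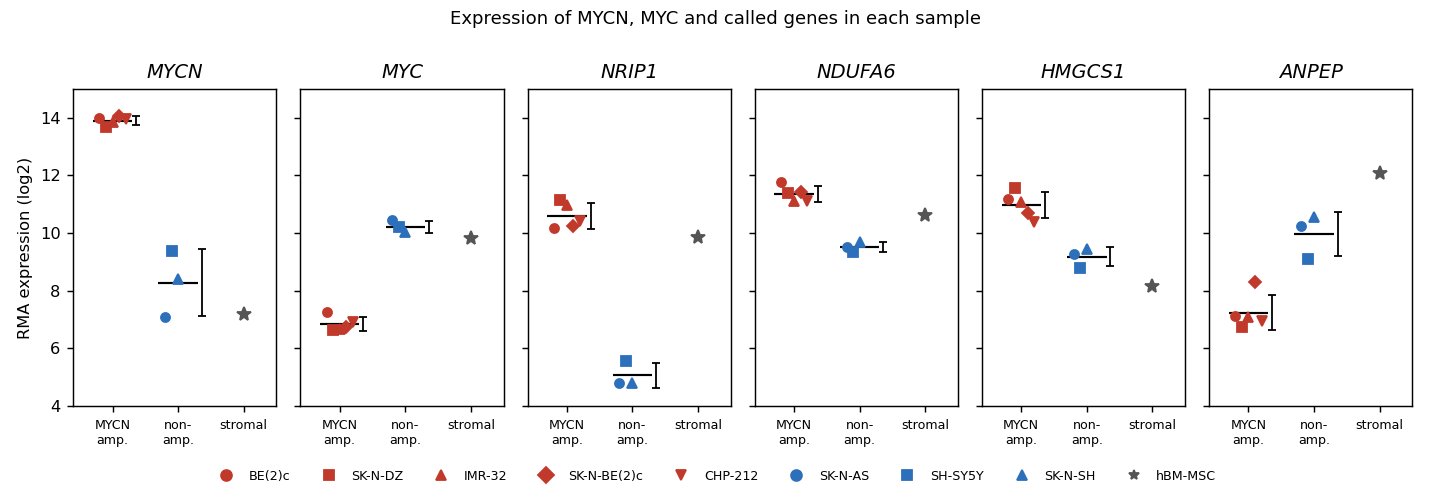
RMA expression (log2) of 6 genes in the 5 MYCN-amplified lines, the 3 non-amplified lines and the stromal sample (hBM-MSC). Points are single arrays, horizontal lines are group means and bars beside them are SDs. MYCN lies between 13.68 and 14.05 in the amplified lines and at most at 9.37 in the others, while MYC averages 6.85 and 10.22.

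RNF217, a RING finger protein, rose by 2.96 log2 units and FLRT3, a membrane adhesion protein, by 2.47 (limma adjusted p = 0.0417 for both). PCLAF, a partner of the replication clamp, rose by 2.33 from 8.81 ± 0.66 to 11.14 ± 0.46, and its stromal level was 5.96 (limma adjusted p = 0.0490). NDUFA6, a subunit of respiratory complex I, rose by 1.86 (limma adjusted p = 0.0184), and HMGCS1, an enzyme of the mevalonate pathway, by 1.81 (limma adjusted p = 0.0490). POP1, a protein of the RNase P and RNase MRP complexes, rose by 1.72, ADCY9, an adenylyl cyclase, by 1.70 and CLN6, a protein of the endoplasmic reticulum, by 1.65, with limma adjusted p of 0.0370, 0.0370 and 0.0490. In each of these genes all 5 amplified lines lay above all 3 others.

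FOXR2, a forkhead transcription factor, fell by 3.07 log2 units (limma adjusted p = 0.0490). TNFAIP6, a secreted hyaluronan-binding protein, fell by 2.92 (limma adjusted p = 0.0417) and ANPEP, a cell-surface aminopeptidase, fell by 2.72 (limma adjusted p = 0.0490), and both were higher still in the stromal cells, at 9.38 and 12.09. NEBL, an actin-binding protein, fell by 2.49, CCDC146 fell by 2.14 and SLC44A3, a choline transporter-like protein, fell by 2.13, with limma adjusted p of 0.0417, 0.0370 and 0.0385. GNG8, a G-protein gamma subunit, fell by 1.92, ORAI3, a subunit of store-operated calcium channels, fell by 1.74 and MERTK, a receptor tyrosine kinase, fell by 1.73, with limma adjusted p of 0.0479, 0.0490 and 0.0490.

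The number of genes past the threshold depended on which lines were counted. It was 10 without BE(2)c, 7 without SK-N-DZ, 11 without IMR-32, 8 without SK-N-BE(2)c, 9 without SK-N-AS, 3 without SH-SY5Y, 2 without SK-N-SH and 58 without CHP-212, and with related lines averaged in both groups only MYC and NRIP1 passed. With the parental line as a random block 7 passed. Other settings gave 43 (mean-variance trend), 46 (robust fit), 48 (quantile normalization), 49 (stricter filter), 57 (no filter), 60 (median centring) and 347 (array weights). Of the 25 named genes past the threshold in the gene test, those 2 also passed it with each line left out in turn, and MYCN passed in 7 of 8 such fits, all but the one without SK-N-SH.

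All 32 members of the cell cycle and DNA replication list had higher means in the amplified lines, by 1.08 log2 units on average. The list rose against other genes (camera adjusted p = 4.96e-19; adjusted p = 0.627 with an estimated correlation). Of its members 2 rose over all genes tested, MCM5, part of the replicative helicase (10.70 ± 0.35 against 9.34 ± 0.23), and GMNN, which encodes geminin (9.36 ± 0.26 against 8.17 ± 0.21), and 28 rose adjusted over the list alone. The groups did not overlap in 23 of the 32. The list mean lay highest in SK-N-DZ and lowest in SK-N-AS, at 0.74 and -1.16 relative to the mean of the 8 lines, and CHP-212 stood at 0.02 next to -0.41 in SH-SY5Y. In the stromal cells it was -3.15.

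Canonical MYC targets rose as a list, with 24 of 30 members higher by mean and a mean difference of 0.33 (camera adjusted p = 5.35e-05; adjusted p = 0.627 with an estimated correlation). BOP1, a ribosome biogenesis factor, was the only member past the threshold over all genes, at 10.31 ± 0.14 against 9.40 ± 0.26, and 10 rose adjusted over the list alone. Fry, which asks whether members move one way without comparing them with other genes, called these lists alone, with adjusted p = 0.0411 for cell cycle and 0.0359 for MYC targets. For both list means the real split gave the largest difference of all 56 (exact permutation p = 0.0179, and 0.205 after adjustment over the lists). The other lists that camera called, described below, did less well in this test. Their unadjusted exact permutation p was 0.0357 for 2p24 neighbours, 0.0714 for chromatin regulators and 0.0893 for interferon-stimulated genes. It was 0.179 for genes reported as repressed by MYCN, 0.321 for extracellular matrix and 0.429 for mesenchymal genes.

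Chromatin regulators rose as a list (mean 0.37, 14 of 18 higher; camera adjusted p = 0.0050; adjusted p = 0.734 with an estimated correlation). No member passed over all genes and 4 rose adjusted over the list alone, namely UHRF1 and DNMT1, which maintain DNA methylation, the histone methyltransferase SUV39H1, and SMARCA4, an ATPase of SWI/SNF remodelling complexes. Their differences were 1.37, 0.75, 0.95 and 0.61 log2 units. Without SK-N-AS the list's mean was 0.23 and its camera adjusted p 0.0827, and the amplified CHP-212 stood at -0.15 relative to the 8 lines, below SH-SY5Y at -0.05. Neighbours of MYCN on 2p24 also rose as a list (mean 0.88, median 0.50, 8 of 10 higher). The list's camera adjusted p was 0.0496, and 0.627 with an estimated correlation. Its 1 member past the threshold, over all genes and adjusted over the list alone, was MYCNOS, at 9.51 ± 0.65 against 5.89 ± 0.71, which overlaps MYCN on the opposite strand, so its signal is uncertain. MYCNOS differed by 3.62 log2 units and so pulls the list's mean above its median. That list's call ended without SK-N-DZ, IMR-32, SK-N-BE(2)c, SK-N-AS or SK-N-SH (camera adjusted p = 0.0755, 0.0908, 0.107, 0.143 and 0.103), while its mean stayed at 0.96, 0.88, 0.85, 0.71 and 0.87. It also ended after quantile normalization (0.0637), median centring (0.0669) and averaging of BE(2)c with SK-N-BE(2)c (0.0642), with means of 0.86, 0.92 and 0.91, and the amplified BE(2)c stood at -0.24, next to SH-SY5Y at -0.21.

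Genes reported as repressed by MYCN fell as a list (mean -0.69, 11 of 13 lower; camera adjusted p = 0.0085; adjusted p = 0.627 with an estimated correlation). None passed over all genes, and DKK3 and NDRG1 fell adjusted over the list alone, by 1.43 and 1.18 log2 units. DKK3, a secreted glycoprotein, read 9.21 ± 0.21 against 10.63 ± 0.86, and NDRG1, a stress-responsive gene, 8.38 ± 0.40 against 9.56 ± 0.57. Without SK-N-SH the mean was -0.27 and the camera adjusted p 0.124. Relative to the mean of the 8 lines the amplified CHP-212 stood at 0.66, above the non-amplified SK-N-AS (0.23) and SH-SY5Y (-0.22), and the other amplified lines between -0.73 and -0.19. Interferon-stimulated genes fell as a list too (mean -0.75, 11 of 12 lower; camera adjusted p = 0.0050; adjusted p = 0.627 with an estimated correlation), with 0 members past the threshold over all genes and 0 adjusted over the list alone in limma, where IFI6 read 8.27 ± 0.97 against 10.27 ± 0.08. That call ended without SK-N-AS (mean -0.42, camera adjusted p = 0.107) or SK-N-SH (mean -0.60, camera adjusted p = 0.0767), and the amplified CHP-212 (0.32) and BE(2)c (0.10) stood above SH-SY5Y (-0.13).

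The extracellular matrix list and the mesenchymal neuroblastoma identity list, genes of the less differentiated state that some neuroblastoma cells take, fell (means -0.76 and -0.41), with camera adjusted p of 0.0347 and 0.0496. With an estimated correlation the adjusted p was 0.861 for both. Of 24 and 34 members 0 passed in limma over all genes, and 0 passed adjusted over the list alone. TNC, a matrix glycoprotein, came nearest at 6.98 ± 0.87 against 10.56 ± 2.04 (limma adjusted p = 0.1002). Lines of 1 group lay far apart in these lists. Relative to the mean of the 8 lines the mesenchymal list stood at 1.01 in the amplified line CHP-212 and between -0.60 and -0.25 in the other amplified lines, and at 0.79 in SK-N-SH, 0.46 in SK-N-AS and -0.47 in SH-SY5Y. Both calls ended when any 1 line other than CHP-212 or SH-SY5Y was left out, with camera adjusted p up to 0.640 and 0.606 without SK-N-SH, where the means shrank to -0.23 and -0.12. Without SK-N-AS the mesenchymal mean was -0.27. In the other such fits the means lay between -0.72 and -0.58 for matrix and between -0.39 and -0.30 for mesenchymal genes. Matrix and mesenchymal means fell further without SH-SY5Y (-1.30 and -0.78) and without CHP-212 (-1.10 and -0.63). Camera adjusted p was then 0.0002 and 0.0003 without SH-SY5Y, and 0.0008 and 0.0006 without CHP-212. Averaging BE(2)c with SK-N-BE(2)c gave camera adjusted p = 0.0778 for both lists (means -0.74 and -0.37), and averaging both related pairs gave 0.0507 (means -0.75 and -0.42).

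**Figure D2:**
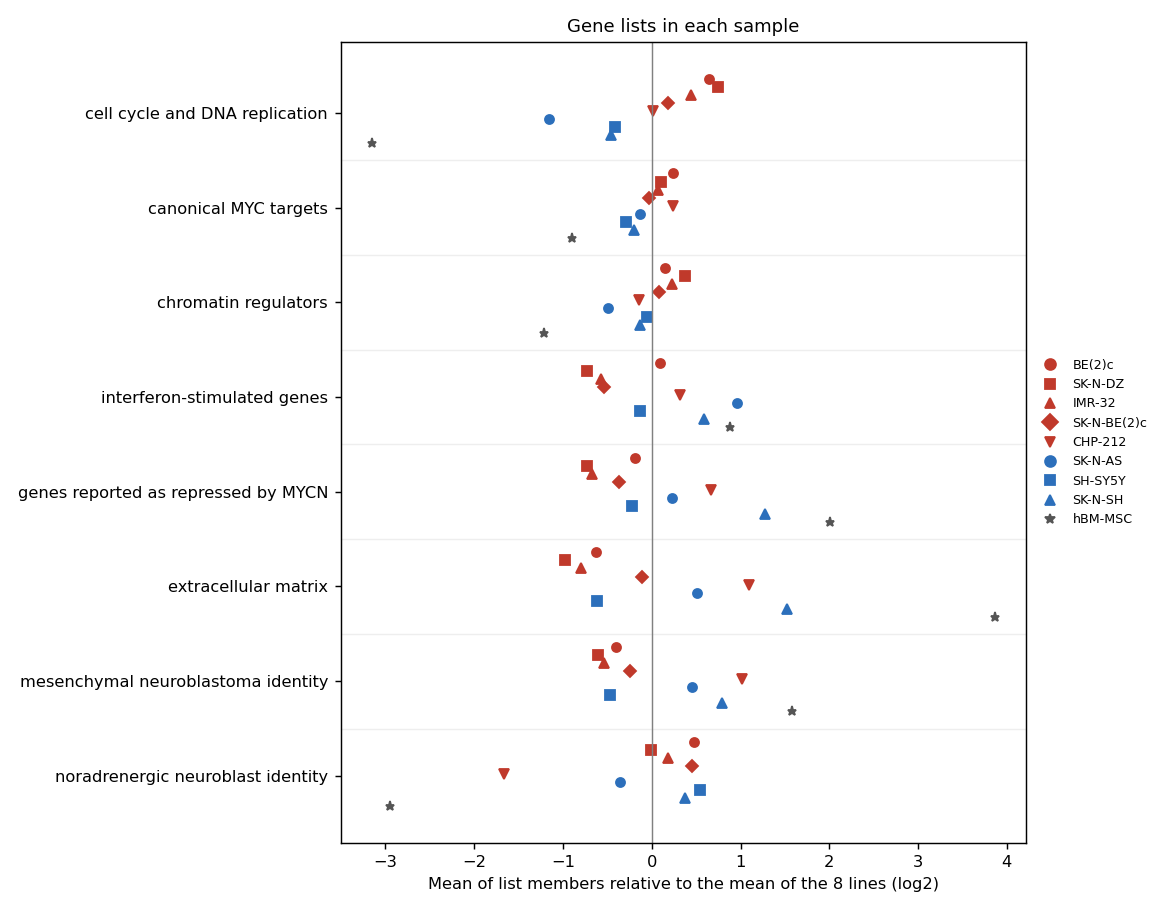
Mean of the members of 8 gene lists in each sample, in log2 units relative to the mean of the 8 neuroblastoma lines. Red marks are MYCN-amplified lines, blue marks are non-amplified lines and the star is the stromal sample (hBM-MSC). The cell cycle mean runs from -1.16 in SK-N-AS to 0.74 in SK-N-DZ, and CHP-212 lies apart from the other amplified lines in the noradrenergic list at -1.66.

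No call was made for the noradrenergic neuroblast identity list, the genes of the sympathetic neuron-like state (mean -0.30, 21 of 28 lower; camera adjusted p = 0.380). TH, the enzyme that begins catecholamine synthesis, read 10.56 ± 1.43 against 7.81 ± 0.18 without passing (limma adjusted p = 0.122). The LIN28B/let-7 list had a camera adjusted p of 0.273, and 2 of its 9 members rose adjusted over the list alone. LIN28B, a repressor of let-7 microRNAs, read 9.59 ± 0.79 against 6.65 ± 1.41, and IGF2BP1, an RNA-binding protein, 10.69 ± 2.22 against 6.63 ± 0.24 (limma adjusted p over all genes = 0.0870 and 0.132). Among p53 targets GDF15, a secreted stress cytokine, fell adjusted over the list alone (7.51 ± 0.68 against 10.21 ± 0.84; limma adjusted p over all genes = 0.0553), and the list's camera adjusted p was 0.112. It was 0.0325 without CHP-212, 0.0052 without SK-N-AS, 0.341 without SK-N-BE(2)c and 0.763 without SK-N-SH, where the list's mean of -0.39 became -0.51, -0.60, -0.26 and -0.19. Polyamine metabolism had 1 member that fell over all genes, AZIN2, an antizyme inhibitor (6.95 ± 0.16 against 7.87 ± 0.10; limma adjusted p = 0.0417), and adjusted over the list alone 1 rose and 1 fell. Its mean difference was 0.04 although camera ranked it downward (adjusted p = 0.962).

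The list of serine, one-carbon and glutamine metabolism had 12 of 16 members higher by mean, a mean difference of 0.38 and a camera adjusted p of 0.0545. That p became 0.0370 without SK-N-BE(2)c, 4.5e-05 without SK-N-AS (mean 0.68) and 0.0370 without the brightness filter, but 0.334 without SH-SY5Y (mean 0.22) and 0.444 without SK-N-SH (mean 0.24). Cytosolic ribosomal proteins had a mean difference of -0.08 (camera adjusted p = 0.133), and 0.0253 without SK-N-BE(2)c, 0.0165 without SK-N-AS and 0.823 without SH-SY5Y. Bone marrow stromal markers (camera adjusted p = 0.115), which include ANPEP as the 1 member that fell, both over all genes and adjusted over the list alone, had 0.0338 without SH-SY5Y, 0.0468 without the brightness filter and 0.513 without SK-N-SH, with means of -0.89, -0.63 and -0.31. YAP/TAZ targets (0.540) and MHC class I presentation (0.169) had camera adjusted p of 0.0338 and 0.0006 without SH-SY5Y (means -1.03 and -0.90). Without SK-N-SH YAP/TAZ targets had 0.622 (mean 0.11), and without SK-N-AS MHC class I had 0.606 (mean -0.10). Only 8 of the 15 fixed MHC class I members were tested, and HLA genes were among those without a usable probeset. Camera adjusted p was 0.517 for ABC transporters, 0.758 for synaptic vesicle genes, 0.962 for osteogenic and adipogenic markers, 0.859 for Schwann and neural crest precursor markers, 0.795 for haematopoietic markers and 0.764 for epithelial markers. None of their members passed in limma over all genes or adjusted over the list alone. Mean and median had opposite signs in the osteogenic and adipogenic list (0.16 and -0.01), and mean and camera direction in the haematopoietic list, whose mean was 0.0015. The 3 tested endothelial markers were too few for a test and their mean differed by 0.03.

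Of 14453 genes, 647 were called at least 4-fold higher in the neuroblastoma lines than in bone marrow stromal cells and 668 lower, without replicates of the stromal sample and so without a test. The stromal value lay outside the range of the 8 lines in 54.0% of genes, where chance gives 22.2% if all arrays are independent, which the related lines are not. STMN2, a microtubule regulator of neurons, averaged 12.79 ± 1.40 in the lines (SD, n = 8) against 5.83, the largest measured difference among genes higher in the lines (6.95 log2 units). PLPPR5, a neuronal membrane protein, was higher by 6.33 log2 units, the transcription factor NFIB by 6.32, the neural adhesion protein CNTN1 by 5.93, NETO2 by 5.64 and the kinesin KIF21A by 5.54. The cell cycle genes DTL and CENPF were higher by 5.84 and 5.59, and SINHCAF by 5.62. H3C2, a replication-dependent histone gene with near-identical copies and therefore uncertain, was higher by 5.71.

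CRYAB, a small heat shock protein, had the largest measured difference in the other direction, 5.42 ± 0.28 in the lines against 13.61 in stromal cells. In 16 of the 20 genes named for this comparison, all but H3C2, TMEM47, CAV1 and ABI3BP, the lower side lay under the 40th percentile of every array, so the size and rank of these differences are limited by background. Differences were -7.86 log2 units for the microfibril protein MFAP5, -7.33 for the endocytic adaptor DAB2, -7.12 for TMEM47, -7.11 for the sulfatase SULF1, -6.89 for the proteoglycan SRGN, -6.75 for caveolin CAV1, -6.75 for the collagen-modifying enzyme PLOD2, -6.70 for VGLL3 and -6.68 for ABI3BP. Single lines departed from the rest, since the highest line reached 13.41 in CAV1, next to the stromal 13.52, and 11.71 in TMEM47 against 14.15.

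Of the 24 lists, 16 lay outside the range of random lists, 7 above and 9 below. The noradrenergic list had a median difference of 3.20 log2 units, with 12 of 28 members called higher and 0 lower, among them the lineage transcription factors GATA3 (5.24) and HAND2 (5.11) and the neuronal RNA-binding protein ELAVL4 (5.05). The cell cycle list had a median of 3.19 and 27 of 32 members called higher, such as CDK1 (5.39), CCNB2 (5.29), TOP2A (5.00) and PLK1 (4.77). The synaptic vesicle list had a median of 1.54, led by RAB3C (4.35), SYT1 (4.26) and SNAP25 (3.48). Medians were 1.34 for the 2p24 neighbours, with VSNL1 and GEN1 called, 1.10 for MYC targets, with MCM7 and POLR1B called, 1.09 for the LIN28B/let-7 list, with IGF2BP3 called, and 0.97 for chromatin regulators, where EZH2 (3.82), UHRF1 (2.97) and DNMT1 (2.27) were called.

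The extracellular matrix list showed the widest gap below, with a median of -4.08 and 25 of 30 members called lower. COL1A2, a chain of type I collagen, was at 7.10 ± 0.16 in the lines and 13.61 in stromal cells, and the crosslinking enzyme LOX differed by -6.60. YAP/TAZ targets had a median of -2.77 with 11 of 15 called lower, including ANKRD1 (-5.92) and CCN2 (-5.83). Bone marrow stromal markers had a median of -2.02, including the chemokine gene CXCL12 (-4.32), and genes reported as repressed by MYCN had -1.95, including THBS1 (-5.67), although NDRG2 was higher in the lines by 2.09. The mesenchymal list had a median of -1.18, with FN1 (-4.61) and CD44 (-3.35) among 12 called lower. MHC class I presentation had -1.10, over 9 of its 15 fixed members and with HLA genes among those without a usable probeset. Interferon-stimulated genes had -0.94, with IFITM3 (-4.41, uncertain because of its close paralogs). Medians were -0.66 for p53 targets, with CDKN1A (-3.17) lower and PMAIP1 (2.96) higher, and -0.52 for serine, one-carbon and glutamine metabolism, with ALDH1L2 (-3.09).

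The 8 lists within the range of random lists were cytosolic ribosomal proteins (median 0.27), polyamine metabolism (0.18), Schwann and neural crest precursor markers (0.02), ABC transporters (-0.0039), endothelial markers (-0.25), haematopoietic markers (-0.26), epithelial markers (-0.41) and osteogenic and adipogenic markers (-0.53). Single members were still called lower in the lines, among them the polyamine acetyltransferase SAT1 (-2.55), the lysosomal protein CD68 (-3.07), the receptor TEK (-3.62) and the keratins KRT7 (-5.66) and KRT14 (-4.18).

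**Figure D3:**
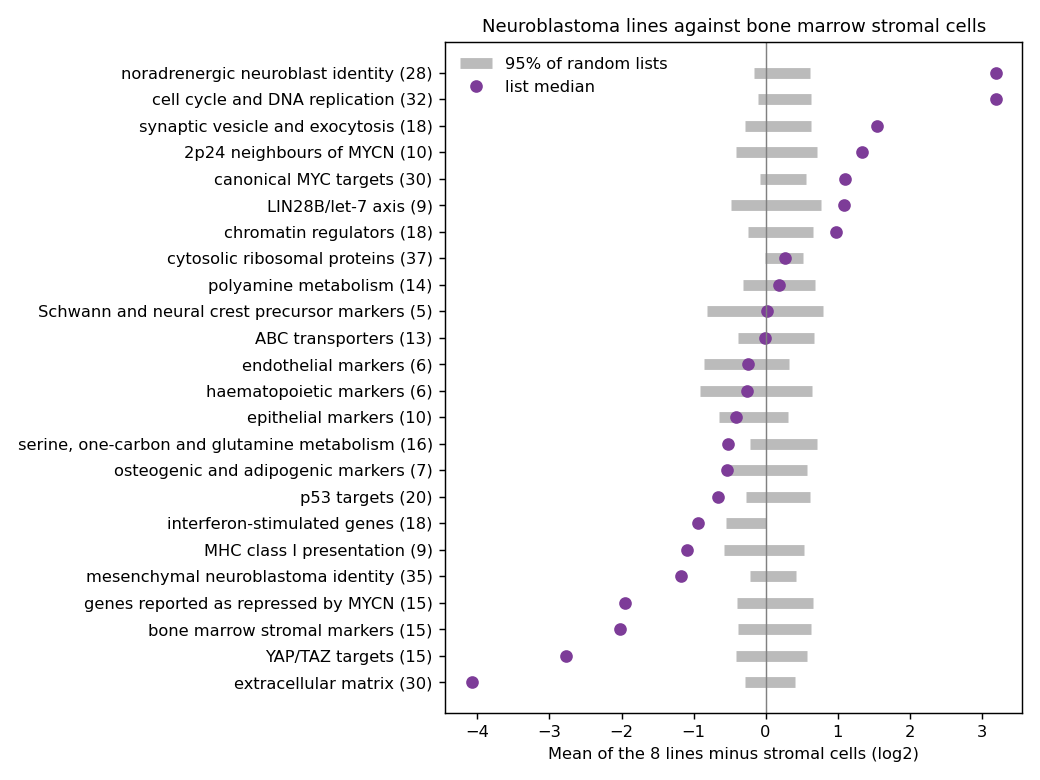
Median over the members of each of 24 gene lists of the mean of the 8 neuroblastoma lines minus the stromal value, in log2 units, with the number of members in parentheses. Grey bars span 95% of random lists matched on mean expression. The noradrenergic list lies highest at 3.20 and the extracellular matrix list lowest at -4.08.

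Across 13853 genes, which are not independent replicates, the stromal array correlated best with SK-N-SH (Pearson r = 0.741), CHP-212 (0.725) and SK-N-AS (0.708), and with the other lines between 0.558 and 0.616. The highest correlations among the lines were 0.920 for SK-N-DZ with IMR-32, 0.913 for IMR-32 with SK-N-BE(2)c, 0.909 for SH-SY5Y with its parental line SK-N-SH and 0.905 for BE(2)c with SK-N-BE(2)c.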

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

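The tests of windows of neighbouring genes against other splits of the lines, and the choice to look at windows at all, came after the data were seen. In 10 of 67 measured levels among the 5 amplified lines, 1 line lay so far from the nearest other that the gap took up more of the group's range than the Dixon 95% limit allows, which chance does in about 5% of groups. The 67 levels are those of named genes and list means, and many of them move together.

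CHP-212 accounted for 4 of the 10. Its noradrenergic list mean was 8.61 against 10.27 in the nearest amplified line (gap 0.775 of the range) and its synaptic vesicle list mean was 8.22 against 9.48 (0.756), both low. Its mesenchymal list mean was 9.86 against 8.61 (0.778) and its YAP/TAZ list mean 9.33 against 7.93 (0.798), both high. Stromal cells mixed into the sample were tested with 130 genes at least 4 log2 units higher in the stromal sample than in any other amplified line. PRRX1 alone would need a stromal share of 54.2%, yet only 43.8% of the 130 genes (57) lay 1 log2 unit or more above the other amplified lines in CHP-212. Abundant stromal transcripts went both ways. COL1A1 was high in CHP-212 (12.86, at most 9.21 in the other amplified lines, 14.00 in stromal cells). Others such as COL1A2 (6.94 in CHP-212 against 13.61 in stromal cells) and CRYAB stayed at the level of the other lines. That argues against mixing with cells like this stromal sample as the cause, and other mesenchymal cells were not covered. The median shift of all genes was -1.11% of the mesenchymal shift of 1.46. Quantile normalization keeps array medians nearly level, so this value cannot decide on an array-wide effect. The noradrenergic mean lay -1.66 log2 units from the lowest other amplified line, which is the gap given above and adds no separate support to a move of CHP-212 from the noradrenergic toward the mesenchymal state. That hypothesis, an array-wide effect and a different culture or origin of the line stay open.

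BE(2)c stood high in POP1 (9.46, next line 8.87, gap 0.752 of the range), in ADCY9 (9.94, next 9.33, 0.810) and in the polyamine list mean (9.96, next 9.79, 0.818). SK-N-BE(2)c, its relative by name, stood high in ANPEP (8.29, next 7.13, 0.757) and TGFBI (8.09, next 6.53, 0.801) and low in DKK3 (8.84, next 9.24, 0.735).

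As to chance in how the lines are grouped, 82 genes passed the threshold in the real split and 1 of the 56 splits, the real one, gave as many, the highest other split, CHP-212, SK-N-AS and SK-N-SH against the rest, giving 43. That count treats related lines as independent. The 12 splits that keep both related pairs together are too few for a share under 5% (82 genes in the real one, at most 13 in another). For the gene lists chance is not excluded, because 22 of the 56 splits gave 8 or more lists and the highest other gave 13.

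Of 262 windows of 50 neighbouring genes, 46 passed in camera (adjusted p under 0.05), 18 higher and 28 lower in the amplified lines, but only 17 of the 46 had an exact permutation p under 0.05 before adjustment (highest 0.375). As to placement, 0 of 1000 random orders of the genes gave as many (highest 1), which argues against random placement. The split with the fewest windows, IMR-32, SK-N-BE(2)c and SH-SY5Y against the rest, still gave 14. The placement result therefore says nothing of MYCN status. A shift shared by SH-SY5Y and SK-N-SH through their parental line stays open, because the median SK-N-AS shift of 0.931 times theirs comes from 1 line and from windows chosen by a difference that includes it, although SK-N-AS shifted the same way in 42 of the 46 and by at least 0.5 times as much in 38. Chance is not excluded for the camera count, since 42 of the 56 splits gave as many windows and the highest gave 91. Windows in which the groups did not overlap numbered 30, against at most 27 in any other split. That count treats related lines as independent, and the real split keeps both related pairs together, so it cannot single out MYCN status. Regions may differ between the lines with or without regard to MYCN status. Copy number differences that track with MYCN status may lie behind part of this, a biological explanation that expression values alone do not test.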

How the results depend on the processing

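Of the alternatives, those that left out SH-SY5Y with CHP-212 and all for windows were chosen after the data were seen. The gene count of 82 stayed within 1.5 times under no filter (57), median centring (60), averaged probesets (81) and separate probesets (90). It was 49 above the 60th percentile, 48 after quantile normalization, 43 with a trend, 46 with robust eBayes, 347 with array weights, 507 at adjusted p under 0.1 and 3 against a minimum change of 1.5-fold. Averaging related lines gave 12 (BE(2)c pair), 3 (SH-SY5Y pair) and 2 (both), a random parental block gave 7, leaving out 1 line gave 2 to 58, and leaving out SH-SY5Y and CHP-212 gave 7. All 82 genes kept their direction with related lines averaged. They were chosen by their difference on these same arrays, so a change of sign was unlikely and this adds no support.

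The list count of 8 was 5 with the BE(2)c pair averaged, 3 to 11 with 1 line left out, 14 without SH-SY5Y and CHP-212, 2 with fry and 0 with an estimated correlation in camera. Under every other alternative it was 6 to 12. The same replicate number did not pair the lines (correlation of deviations 0.075, 0.212 and -0.086). With the replicate block, 0 genes passed in limma (2299 at unadjusted p under 0.05) and 12 lists in camera. The 2p24 list lost its call (camera adjusted p = 0.0631, mean 0.74). For MYCN the block used only the 3 pairs of lines with the same number, without SK-N-BE(2)c and CHP-212. Over these pairs MYCN differed by 5.55 (exact test by flipping signs within pairs, p = 0.25, the smallest possible). MYCN differed by 5.89 with related lines averaged (p = 0.0667, exact permutation) and by 5.02 to 6.16 with 1 line left out.

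Means of lists without a call changed sign as follows, and the cause was not tested. ABC transporters: -0.0173 (quantile normalization, and both pairs averaged), -0.0214 (SH-SY5Y pair averaged), -0.0781 (array weights), -0.00379 (parental block), -0.0386 (replicate block), -0.18 (SH-SY5Y and CHP-212 out) and -0.11 to 0.11 (1 line out). Haematopoietic markers: -0.00665 (no filter), -0.0508 (array weights), -0.0869 (both lines out) and -0.0471 to 0.0623 (1 line out). Noradrenergic: 0.0318 (replicate block), 0.25 (both lines out) and -0.57 to 0.0914 (1 line out). Osteogenic and adipogenic: -0.0701, -0.0953 and -0.0357 to 0.32 in the same settings. Schwann and neural crest: -0.0525 (array weights) and -0.26 to 0.25. Ribosomal proteins: 0.0370 (both lines out) and -0.16 to 0.0195. Polyamine: -0.00317 (both pairs averaged). With 1 line out, YAP/TAZ targets spanned -1.03 to 0.11, epithelial markers -0.30 to 0.0416 and synaptic vesicle genes -0.23 to 0.52. Genes without a call that changed sign were PPARG (-0.0938 with the SH-SY5Y pair averaged, -0.0506 with the replicate block, -0.89 with both lines out, -0.35 to 1.46 with 1 line out), SOX10 (-0.0449 with both lines out, -0.0186 to 0.0774), CLDN3 (-0.15 to 0.0339), GFRA3 (-1.88 to 0.13), KRT18 (-0.81 to 0.0395) and NLRC5 (-0.43 to 0.0264).

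Among all other named-gene values between the groups, 1747 kept direction and side of the threshold, 332 lost the call and 7 gained it. For lists 413 kept both, 29 lost and 27 gained a call. Only the 25 named genes past the threshold could lose a call, and the 1747 include genes not called in the main fit. MYC and NRIP1 passed in 21 of 22 alternatives and MYCN in 19, while each other of the 25 genes passed in at most 13. The stromal count of 1315 was 595 at 8-fold and 3397 at 2-fold, 904 in limma with the lone stromal array assumed to vary like the lines (902 shared), and 1250 to 1405 otherwise. The 16 lists apart stayed 16 in all 12 alternatives, but all of these kept the same stromal array, so differences between stromal samples were not covered. SRGN moved to -7.03 after quantile normalization. Windows numbered 38 to 54. Probesets near the array background limit differences in dim genes.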

Other observations

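SH-SY5Y was derived from SK-N-SH, and their arrays differed mostly in 1 direction. Of 13661 genes, 202 were at least 4-fold higher in SK-N-SH and 24 at least 4-fold higher in SH-SY5Y, with 1 array each and no test. All 24 extracellular matrix members were higher in SK-N-SH, by 2.14 log2 units on average, and 12 of them at least 4-fold. Of 34 mesenchymal members 27 were higher, by 1.27 on average, and 8 at least 4-fold. The noradrenergic and cell cycle lists differed by -0.18 and -0.05 on average, with 0 of 28 and 0 of 32 members differing 4-fold, and the synaptic vesicle list by -0.65, with 1 of 18 members higher in SK-N-SH. For comparison, BE(2)c and SK-N-BE(2)c differed at least 4-fold in 280 genes, 84 higher in the former, and SK-N-DZ and IMR-32, which are not known relatives, in 224.

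Mesenchymal genes were high in lines of both groups. PRRX1, a mesenchymal transcription factor, read 12.09 in SK-N-SH, 10.05 in CHP-212 and 9.85 in SK-N-AS, against 5.83 to 6.32 in the other 5 lines and 10.89 in stromal cells. ANXA1, an annexin, read 13.93 in CHP-212, 12.93 in SK-N-SH and 11.97 in SK-N-AS, at most 5.97 elsewhere among the lines, and 13.94 in stromal cells. In CHP-212 the noradrenergic genes PHOX2A (8.02) and DBH (7.76) lay near the stromal 7.67 and 7.78, while GATA3 (11.96) and HAND2 (11.68) lay at the level of the other lines. PRRX1, ANXA1, PHOX2A and DBH were chosen after their values were seen.

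The sharpest window, on chromosome 22 between SLC25A17 and RTL6, was 0.56 log2 units higher in the amplified lines, with 44 of 50 genes higher (camera adjusted p = 1.49e-11). Relative to the amplified mean its average lay between -0.03 and 0.03 in the 5 amplified lines and at -0.63, -0.52 and -0.54 in SK-N-AS, SH-SY5Y and SK-N-SH. It held 6 of the 10 called genes of chromosome 22, and all 10 were higher in the amplified lines. On chromosome 1 the window from MUL1 to MAN1C1 was lower by mean in the amplified lines (-0.44, camera adjusted p = 2.43e-08). Chromosome 7 as a whole was lower too (-0.21 over 617 genes, camera adjusted p = 2.71e-06), mostly through the related lines SH-SY5Y and SK-N-SH at 0.29 and 0.26, while SK-N-AS at 0.09 stood next to the amplified BE(2)c at 0.08.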
